A study of Mus musculus with 15 samples.

How the data were processed

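Total RNA of mouse primary myoblasts differentiated to myotubes was measured on Affymetrix mouse exon arrays, 3 arrays in each of 5 groups. The cells were transduced at 48 h of differentiation at a multiplicity of infection of 100, the medium was changed after 12 h and RNA was taken at about 60 h. RNA was converted to biotin-labelled sense-strand cDNA. The values are log2 signals per transcript cluster, as deposited by the authors, in a table of 23332 clusters and 15 arrays. The submitters' processing notes name Partek, and its version, the background correction, the normalization and the summarization are not given in the sources used here. The array distributions were similar but not identical, with medians from 5.476 to 5.659 log2, so the values had not been forced to 1 distribution. They were used as deposited. Scanner files were outside the data used here, so other background corrections could not be tried. The genome build is not given in the sources used here, so no positions are reported.

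Arrays were grouped by the isoform in their titles. For PGC-1a4 the source name of the labels says isoform 1, in conflict with the titles, and the titles were followed. Replicate numbers were not taken as pairs: 10 of 30 same-numbered pairs of arrays had correlated deviations above 0.1, the correlations ran from -0.22 to 0.36, and for 6 of 15 arrays the closest array of another group had the same number. The replicate 1 arrays of GFP, PGC-1a1, PGC-1a3 and PGC-1a4 were correlated at 0.19 to 0.32 with each other, and at -0.04 to 0.04 with that of PGC-1a2. A factor shared by those replicate 1 arrays is therefore not ruled out. Of the 23332 clusters, 14996 carried exactly 1 gene symbol, 1019 several and 7317 none. All were tested, and those with 1 symbol named 14860 genes. Of these genes 135 had more than 1 cluster, and 0 of the 135 were called in opposite directions. For list tests the cluster with the highest mean stood for the gene.

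All 15 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 10 residual degrees of freedom and 2.09 prior degrees of freedom). The 10 contrasts were the 4 isoforms against GFP and the 6 pairs of isoforms, with an F-test over the 5 groups. Changes are differences of group means in log2, the first group minus the second, with the moderated SE (n = 3 per group). P-values are two-sided and were adjusted by Benjamini-Hochberg over all clusters within each contrast, and a cluster was called at an adjusted p under 0.05. On a single gene an exact test of 3 arrays against 3 cannot go below 0.1, so the calls rest on the pooled variance model.

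A total of 28 gene lists with 680 genes, of which 560 had a cluster and 19 were on more than 1 list, were written before the data were examined, as were the contrasts, the rule for named genes and the alternatives, except the one stated as added. List genes without a cluster of exactly 1 symbol included myosin heavy chain genes. These were Myh1, Myh2 and Myh4 (fast fibre), Myh7 (slow fibre), and Myh3 and Myh8 (myogenic differentiation). The lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists within a contrast. Each was tested again with the correlation estimated from the data, and with fry, which asks whether a list's genes move 1 way without comparing them with other genes. Named genes are the 8 largest rises and 8 largest falls of each isoform against GFP, and the 4 and 4 of each isoform pair, among called clusters with exactly 1 symbol and no overlap between the groups. Uncharacterised and highly repeated loci were passed over. From each list, up to 4 members with the smallest p could be named, and Ppargc1a was reported on its own.

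The alternatives were quantile normalization, median centring, filters at percentile 25 or 50 of all values on at least 3 arrays, only clusters with 1 symbol, only the 2 groups of a contrast, a variance trend with robust estimation, array weights, the replicate number as a block, the mean of a gene's clusters, and leaving out each array. For lists the trend alternative used the variance trend only. The interquartile range of each array as a covariate was added after the data were seen. Shared controls were examined with 20 simulated data sets in which no group differed. The fit was tested on simulated data with the design of these arrays and, for each cluster, 1 pooled spread shared by all groups. In PGC-1a4 against GFP it called 34 of 67 clusters shifted by 0.5 log2 (50.7%) and 55 of 67 shifted by 1 (82.1%). It called 63 of 66 shifted by 2 (95.5%), and 7 unshifted clusters. In a simulated contrast with no shift 0 were called. A list of 50 shifted by 0.3 log2 had a camera p of 2.3e-27, and an unshifted list one of 0.78. The clusters were simulated as independent of each other, so this does not test whether the preset correlation holds in the real lists. GFP was simulated with the same spread as the isoform groups. Its median within-group SD was 0.176 log2 in the data, against 0.113 to 0.137 in those groups. False calls from this difference were therefore not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.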

Results

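Gene expression was measured in mouse myotubes, the multinucleate cells formed when primary myoblasts (muscle precursor cells) differentiate in culture. At 48 h of differentiation the cells received adenovirus at a multiplicity of infection of 100. The virus carried GFP alone, which is the control, or 1 of 4 isoforms of the transcriptional coactivator PGC-1a, named PGC-1a1 to PGC-1a4. RNA was taken 60 h after transduction. Each of the 5 groups had 3 arrays, and each of the 15 arrays gave a log2 signal for 23332 transcript clusters, each a set of probes for 1 gene or locus. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples. The series title asks how the isoforms act on splicing of target genes. A single value per cluster cannot show splicing. It pools a gene's probes, so a change in the exons used could also move it. The comparisons here concern this pooled signal, which is read as the gene's level.

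Array medians lay between 5.476 and 5.659 log2, and the number of arrays, 3 per group, limits the precision. The limma F-test over the 5 groups called 7295 clusters, 31.3% of all. On the first principal component (24.7% of the variance) PGC-1a1 and PGC-1a4 arrays scored from 8.0 to 34.9, and PGC-1a2 and PGC-1a3 arrays from -28.8 to -10.8. GFP replicate 2 stood apart from the other GFP arrays on the second component (15.5%), at 40.9 against -14.3 and -7.0. Its correlation with the other GFP arrays was 0.982 and 0.983 across clusters, which are not independent replicates, while GFP replicates 1 and 3 reached 0.991 with each other. Its highest correlation was with a PGC-1a1 array, 0.988. Against the other GFP arrays, the median difference in that array was -0.25 log2 over genes of branched-chain amino acid catabolism and -0.19 over cell cycle genes. Markers of endothelial cells differed by 0.37, of fibroblasts by 0.24 and of adipocytes by 0.24. Median within-group SD was 0.176 log2 in GFP and between 0.113 and 0.137 in the isoform groups.

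The introduced gene itself was compared first. Ppargc1a, which encodes PGC-1a, had a signal of 8.53 ± 0.38 log2 (SD, n = 3) in GFP cultures, 12.61 ± 0.06 in PGC-1a1 and 10.46 ± 0.14 in PGC-1a4. It rose by 4.08 ± 0.16 (log2 change ± SE, adjusted p = 6.2e-08) in PGC-1a1 and by 1.93 ± 0.16 (adjusted p = 8.1e-06) in PGC-1a4. The signal was 8.88 ± 0.02 in PGC-1a2 and 8.94 ± 0.18 in PGC-1a3, differences from GFP of 0.35 ± 0.16 (adjusted p = 0.22) and 0.42 ± 0.16 (adjusted p = 0.14) that did not pass. Without GFP replicate 1 these were 0.53 (adjusted p = 0.043) and 0.59 (adjusted p = 0.03), both past the threshold. Without GFP replicate 2 they were 0.14 and 0.21. The cluster's signal pools probes that an isoform may lack, so it does not compare doses.

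**Figure D1:**
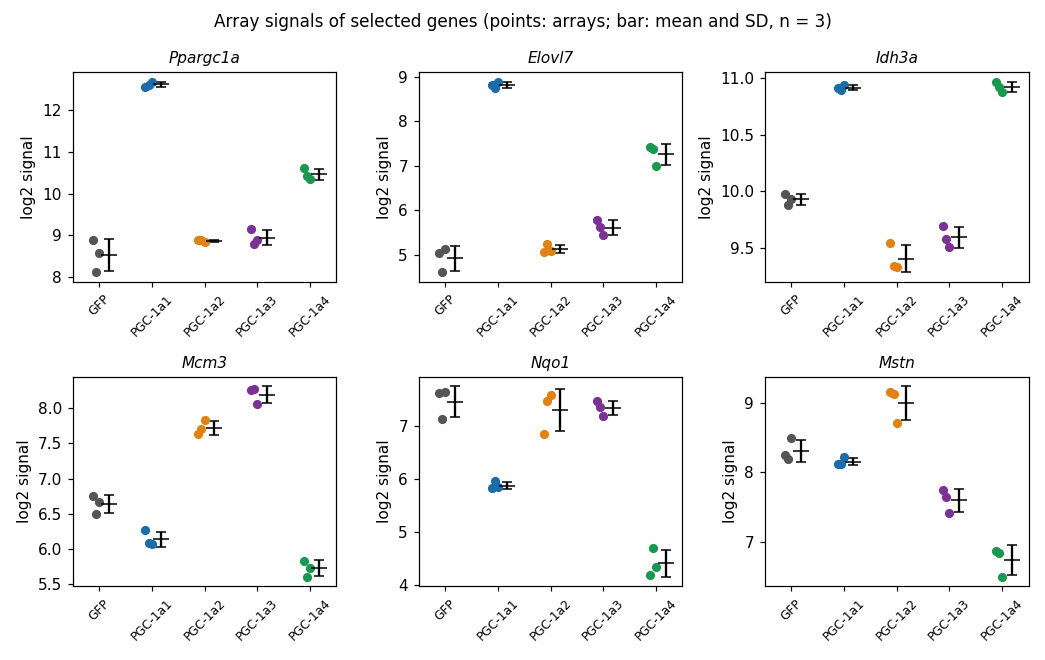
Log2 signal of 6 genes on each of the 15 arrays, by group, with points for arrays and a bar for the mean and SD (n = 3). Ppargc1a averaged 12.61 in PGC-1a1 and 8.88 in PGC-1a2, Mcm3 averaged 8.19 in PGC-1a3 against 6.64 in GFP, and Nqo1 averaged 4.42 in PGC-1a4 against 7.46 in GFP.

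PGC-1a1 against GFP asks what the full-length isoform changed. Genes that rose included Idh3a and Ogdh of the TCA cycle and Ndufa8 of the respiratory chain, and those that fell included Casq1 of the fast fibre and Slc7a11, the cystine transporter gene. The fatty acid elongase gene Elovl7 rose by 3.90 ± 0.15 log2 (SE, n = 3 per group, adjusted p = 6.2e-08), and Nudt19, which encodes a peroxisomal coenzyme A hydrolase, by 1.82 ± 0.13. Hspa1a, the inducible heat shock protein gene, changed by -1.83 ± 0.10 (adjusted p = 1.4e-06), and Nqo1, an antioxidant quinone reductase gene, by -1.58 ± 0.20. In all, 1596 clusters passed, 1036 higher and 560 lower, and 69 of them differed by 2-fold or more (44 higher, 25 lower).

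Among the largest rises in PGC-1a1 were also Hpdl (2.50 ± 0.26), Cend1 (2.22 ± 0.16), the uridine phosphorylase gene Upp1 (1.67 ± 0.11), the carbonic anhydrase gene Car2 (1.62 ± 0.14), Pipox (1.57 ± 0.15), a peroxisomal sarcosine oxidase gene, and the glutaredoxin gene Glrx (1.47 ± 0.12). Pipox averaged 3.87 log2 in GFP, below the lower quartile of each GFP array (3.915 to 4.047), so it is not shown to be above background there. Large falls included the uroplakin gene Upk1b (-2.06 ± 0.17), the prostaglandin synthase gene Ptgs2 (-1.65 ± 0.21), Slc7a11 (-1.32 ± 0.24), the galectin gene Lgals4 (-1.26 ± 0.14) and Ctrb1 (-1.19 ± 0.10). Tas2r135, a taste receptor gene, changed by -1.23 ± 0.25 (adjusted p = 0.012), a call lost without PGC-1a1 replicate 3 (adjusted p = 0.053).

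In the respiratory chain, 30 of 52 measured genes rose and 0 fell (37 and 0 adjusted over the list alone) in PGC-1a1. The oxidative phosphorylation median was 0.32 log2 (adjusted p = 2.7e-21 by camera, and adjusted p = 0.035 with an estimated correlation), with Ndufa8 at 0.71 ± 0.06 and Cyc1 at 0.56 ± 0.07. In the TCA cycle, 18 of 21 measured genes rose and 0 fell (20 and 0 adjusted over the list alone), among them Idh3a (0.99 ± 0.07), Ogdh (0.92 ± 0.06) and Cs (0.55 ± 0.06), the citrate synthase gene. The TCA cycle median was 0.47 log2 (adjusted p = 3.7e-22 by camera, and adjusted p = 0.036 with an estimated correlation). In the malate-aspartate shuttle and kynurenine aminotransferase list, which moves reducing equivalents into mitochondria and degrades kynurenine, 6 of 8 measured genes rose and 0 fell (7 and 0 adjusted over the list alone). That list's median was 0.56 log2 (adjusted p = 4.4e-09 by camera, and adjusted p = 0.039 with an estimated correlation), with Got1 at 0.72 ± 0.06 and Kyat1 at 0.80 ± 0.12. In fatty acid oxidation, 12 of 23 measured genes rose and 0 fell (14 and 1 adjusted over the list alone), including the carnitine transferase gene Cpt1a (0.86 ± 0.06) and Etfdh (1.03 ± 0.09). The fatty acid oxidation median was 0.31 log2 (adjusted p = 3e-09 by camera, and adjusted p = 0.057 with an estimated correlation). In branched-chain amino acid catabolism, 9 of 20 measured genes rose and 0 fell (10 and 1 adjusted over the list alone), including Mcee (0.76 ± 0.07) and Bckdhb (0.76 ± 0.10). The branched-chain amino acid median was 0.32 log2 (adjusted p = 1.1e-06 by camera, and adjusted p = 0.36 with an estimated correlation).

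In cholesterol and fatty acid synthesis, 6 of 23 measured genes rose and 0 fell (8 and 0 adjusted over the list alone) in PGC-1a1, including the elongase gene Elovl6 (1.35 ± 0.16) and Nsdhl (0.64 ± 0.09). The cholesterol and fatty acid synthesis median was 0.24 log2 (adjusted p = 0.00031 by camera, and adjusted p = 0.44 with an estimated correlation), and the adjusted p was 0.091 with array weights. Among angiogenic factors, 5 of 13 measured genes rose and 0 fell (6 and 0 adjusted over the list alone), including Esrra (0.97 ± 0.08), a nuclear receptor gene that the mitochondrial genome list also holds. The angiogenic factor median was 0.21 log2 (adjusted p = 0.0057 by camera, and adjusted p = 0.056 with an estimated correlation). In mitochondrial dynamics, 5 of 13 measured genes rose and 0 fell (6 and 2 adjusted over the list alone), including the fusion gene Mfn1 (1.12 ± 0.09). The mitochondrial dynamics median was 0.25 log2 (adjusted p = 0.0047 by camera, and adjusted p = 0.33 with an estimated correlation), and the adjusted p was 0.096 with array weights and 0.057 with the interquartile-range covariate. In mitochondrial genome maintenance and transcription, 5 of 23 measured genes rose and 1 fell (6 and 1 adjusted over the list alone). The mitochondrial genome median was 0.11 log2 (adjusted p = 0.0074 by camera, and adjusted p = 0.49 with an estimated correlation), and the adjusted p was 0.093 with a filter at the median signal, 0.33 with array weights and 0.51 with the interquartile-range covariate, and 0.22 without GFP replicate 2 and 0.068 without PGC-1a1 replicate 1.

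Among fast-fibre contractile genes, 0 of 14 measured genes rose and 4 fell (0 and 7 adjusted over the list alone) in PGC-1a1, including the calsequestrin gene Casq1 (-0.78 ± 0.10) and the troponin gene Tnni2 (-0.44 ± 0.06). The fast-fibre median was -0.19 log2 (adjusted p = 0.00016 by camera, and adjusted p = 0.26 with an estimated correlation). The myosin heavy chain genes Myh1, Myh2 and Myh4 of this list were not measured. Among p53 targets, 0 of 19 measured genes rose and 3 fell (1 and 6 adjusted over the list alone), including Gadd45a (-0.65 ± 0.10). The p53 target median was -0.09 log2 (adjusted p = 0.0074 by camera, and adjusted p = 0.33 with an estimated correlation). In myogenic differentiation, 0 of 15 measured genes rose and 2 fell (0 and 4 adjusted over the list alone), with Myf6 at -0.49 ± 0.08. The myogenic median was -0.11 log2 (adjusted p = 0.0074 by camera, and adjusted p = 0.44 with an estimated correlation), and the adjusted p was 0.075 without GFP replicate 1. At the neuromuscular junction, 1 of 20 measured genes rose and 5 fell (1 and 5 adjusted over the list alone), including Erbb3 (-0.83 ± 0.11). The neuromuscular junction median was -0.11 log2 (adjusted p = 0.029 by camera, and adjusted p = 0.49 with an estimated correlation), and the adjusted p was 0.072 with median centring and 0.051 with only the 2 groups fitted, and 0.084 without GFP replicate 1, 0.066 without GFP replicate 3 and 0.056 without PGC-1a1 replicate 2. Among cell cycle genes, 2 of 30 measured genes rose and 3 fell (3 and 4 adjusted over the list alone), with the ribonucleotide reductase gene Rrm1 higher (0.67 ± 0.07) and the helicase gene Mcm2 lower (-0.44 ± 0.06). The cell cycle median was -0.16 log2 (adjusted p = 0.044 by camera, and adjusted p = 0.7 with an estimated correlation), and the adjusted p was 0.082 with quantile normalization, 0.052 with a variance trend and 0.36 with fry in place of camera, and 0.3 without GFP replicate 1, 0.11 without GFP replicate 3, 0.083 without PGC-1a1 replicate 2 and 0.23 without PGC-1a1 replicate 3.

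In PGC-1a1, 14 of the 28 lists passed, 9 up and 5 down, and 3 with an estimated correlation. With only the 2 groups in the fit, 393 clusters passed, and the adjusted p was 0.082 for Gadd45a, 0.062 for Myf6 and 0.082 for Mcm2. Leaving out PGC-1a1 replicate 1, 2 or 3 gave 1052, 951 and 957 clusters, array weights gave 2994 (1418 higher, 1576 lower), the interquartile-range covariate gave 2430, and median centring gave 1110 higher and 214 lower.

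PGC-1a2 against GFP asks what this shorter isoform changed. The genes that rose included Mcm3, Mcm4 and Mcm6 of the replicative helicase, and those that fell included Bckdhb of branched-chain amino acid breakdown and Msmo1 of cholesterol synthesis. Pla2g7, which encodes a lipoprotein-associated phospholipase, rose by 2.61 ± 0.10 log2 (SE, n = 3 per group, adjusted p = 9.9e-08), and the cell adhesion gene Selp by 2.27 ± 0.10 (adjusted p = 2.6e-07). The matrix protein gene Postn changed by -1.72 ± 0.12 (adjusted p = 2.1e-05) and the secreted hormone gene Fgf21 by -1.61 ± 0.19 (adjusted p = 0.00037). In all, 2177 clusters passed, 1064 higher and 1113 lower, and 73 of them differed by 2-fold or more (55 higher, 18 lower).

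Other large rises in PGC-1a2 were Palmd (2.29 ± 0.21), Lgr5 (2.04 ± 0.11), a Wnt pathway receptor gene, the fatty acid desaturase gene Scd1 (1.92 ± 0.16), the TWEAK receptor gene Tnfrsf12a (1.83 ± 0.12), Prr9 (1.76 ± 0.17) and Angptl4 (1.73 ± 0.20), which encodes an inhibitor of lipoprotein lipase. In GFP, Palmd and Prr9 averaged 3.77 and 3.67 log2, below the lower quartile of each array (3.857 to 4.047), so they are not shown to be above background there. Other large falls were the mitochondrial adenylate kinase gene Ak4 (-1.44 ± 0.17), Tdrkh (-1.38 ± 0.10), the secreted glutathione peroxidase gene Gpx3 (-1.35 ± 0.10), the sterol oxidase gene Msmo1 (-1.14 ± 0.07) and the muscle-secreted factor gene Ostn (-1.13 ± 0.15). Nubpl, needed for assembly of respiratory complex I, changed by -1.29 ± 0.35 (adjusted p = 0.04). That call was lost without GFP replicate 1 (adjusted p = 0.13), without GFP replicate 3 (0.14), without PGC-1a2 replicate 1, 2 or 3 (0.072, 0.078 and 0.14) and with median centring (0.071).

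Among cell cycle genes, 10 of 30 measured genes rose and 0 fell (15 and 0 adjusted over the list alone) in PGC-1a2, and those with the lowest p encode the replicative helicase, including Mcm3 (1.09 ± 0.10), Mcm4 (1.02 ± 0.11) and Mcm6 (0.96 ± 0.12). The cell cycle median was 0.29 log2 (adjusted p = 2.1e-09 by camera, and adjusted p = 0.43 with an estimated correlation). Among splicing factors, 9 of 38 measured genes rose and 0 fell (15 and 0 adjusted over the list alone), including Mbnl3 (0.69 ± 0.12) and Ptbp1 (0.48 ± 0.09). The splicing factor median was 0.12 log2 (adjusted p = 1e-04 by camera, and adjusted p = 0.44 with an estimated correlation). In the muscle growth list, 7 of 24 measured genes rose and 1 fell (9 and 1 adjusted over the list alone), including Smad7 (0.77 ± 0.07), an inhibitor of TGF-beta signalling, and the growth inhibitor gene Mstn (0.69 ± 0.14). The muscle growth median was 0.12 log2 (adjusted p = 0.0011 by camera, and adjusted p = 0.43 with an estimated correlation). The list also holds Adgrg1 (-0.72 ± 0.08), a receptor gene, and Fst (0.40 ± 0.08), which encodes a myostatin antagonist. With an inhibitor and its antagonist on the same list, its direction is not a direction of growth.

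In branched-chain amino acid catabolism, 0 of 20 measured genes rose and 11 fell (0 and 18 adjusted over the list alone) in PGC-1a2, including Mmut (-0.64 ± 0.07) and Bckdhb (-0.70 ± 0.10). The branched-chain amino acid median was -0.35 log2 (adjusted p = 2.1e-09 by camera, and adjusted p = 0.43 with an estimated correlation). In oxidative phosphorylation, 0 of 52 measured genes rose and 10 fell (0 and 20 adjusted over the list alone), including Ndufs4 (-0.32 ± 0.06) and Ndufs6 (-0.57 ± 0.11). The oxidative phosphorylation median was -0.18 log2 (adjusted p = 2.7e-05 by camera, and adjusted p = 0.43 with an estimated correlation). In cholesterol and fatty acid synthesis, 1 of 23 measured genes rose and 9 fell (2 and 13 adjusted over the list alone), with Nsdhl at -0.68 ± 0.09 and Hmgcs1 at -0.54 ± 0.08, against the rise of Scd1. The cholesterol and fatty acid synthesis median was -0.33 log2 (adjusted p = 0.00034 by camera, and adjusted p = 0.45 with an estimated correlation). Among slow-fibre contractile genes, 0 of 10 measured genes rose and 3 fell (0 and 3 adjusted over the list alone), including the myoglobin gene Mb (-0.45 ± 0.09). The slow-fibre median was -0.14 log2 (adjusted p = 0.0028 by camera, and adjusted p = 0.43 with an estimated correlation).

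In the TCA cycle, 0 of 21 measured genes rose and 4 fell (0 and 7 adjusted over the list alone) in PGC-1a2, including Idh3a (-0.53 ± 0.07). The TCA cycle median was -0.15 log2 (adjusted p = 0.0041 by camera, and adjusted p = 0.49 with an estimated correlation), and the adjusted p was 0.06 without GFP replicate 1. In mitochondrial dynamics, 0 of 13 measured genes rose and 3 fell (0 and 3 adjusted over the list alone), including the mitophagy genes Pink1 (-0.45 ± 0.07) and Bnip3 (-0.66 ± 0.10). The mitochondrial dynamics median was -0.13 log2 (adjusted p = 0.0094 by camera, and adjusted p = 0.45 with an estimated correlation). In glycolysis and glucose uptake, 1 of 18 measured genes rose and 6 fell (1 and 7 adjusted over the list alone), with Pdk1 at -0.64 ± 0.07, Pfkp at -0.58 ± 0.07 and Pdk4, a kinase gene that restrains pyruvate oxidation, at 0.71 ± 0.13. The glycolysis median was -0.19 log2 (adjusted p = 0.017 by camera, and adjusted p = 0.45 with an estimated correlation). In fatty acid oxidation, 2 of 23 measured genes rose and 4 fell (2 and 9 adjusted over the list alone), with Cpt1a (0.60 ± 0.06) and Lpl (0.58 ± 0.07) higher and Acadvl lower (-0.39 ± 0.07). The fatty acid oxidation median was -0.21 log2 (adjusted p = 0.017 by camera, and adjusted p = 0.47 with an estimated correlation), and the adjusted p was 0.063 without GFP replicate 1. In the malate-aspartate shuttle and kynurenine aminotransferase list, 0 of 8 measured genes rose and 3 fell (0 and 4 adjusted over the list alone), including Kyat1 (-0.65 ± 0.12). Its median was -0.18 log2 (adjusted p = 0.03 by camera, and adjusted p = 0.45 with an estimated correlation), and the adjusted p was 0.059 with a filter at the median signal, and 0.1 without GFP replicate 3.

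In PGC-1a2, 12 of the 28 lists passed, 3 up and 9 down, and 0 with an estimated correlation. With only the 2 groups in the fit, 173 clusters passed, and the adjusted p was 0.14 for Nubpl, 0.07 for Mbnl3, 0.11 for Ptbp1, 0.1 for Mstn, 0.056 for Adgrg1, 0.13 for Fst, 0.056 for Mmut, 0.13 for Ndufs4, 0.056 for Ndufs6, 0.073 for Nsdhl, 0.072 for Hmgcs1, 0.082 for Mb, 0.069 for Idh3a, 0.077 for Pink1, 0.064 for Bnip3, 0.07 for Pfkp, 0.068 for Pdk4, 0.052 for Cpt1a, 0.13 for Acadvl and 0.07 for Kyat1. Leaving out GFP replicate 3 gave 1340 clusters, leaving out PGC-1a2 replicate 2 or 3 gave 1231 and 1304, median centring gave 1354, array weights gave 3492 and the interquartile-range covariate gave 3350. Which direction held more clusters turned too: 789 were higher and 565 lower with median centring, 985 and 786 without GFP replicate 1, 730 and 610 without GFP replicate 3 and 699 and 605 without PGC-1a2 replicate 3, against 819 and 1303 without GFP replicate 2.

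PGC-1a3 against GFP asks the same of the other short isoform. The genes that rose included those of the replicative helicase, and those that fell included Pln and Myl2 of slow-fibre contraction and Dmd of the muscle membrane. The helicase genes Mcm3 and Mcm6 rose by 1.56 ± 0.10 log2 (SE, n = 3 per group, adjusted p = 3.1e-05) and 1.15 ± 0.12 (adjusted p = 3e-04). Pln, which encodes the calcium pump regulator phospholamban, changed by -1.39 ± 0.19 (adjusted p = 0.0015), and the dystrophin gene Dmd by -1.11 ± 0.13 (adjusted p = 0.00057). In all, 1865 clusters passed, 1171 higher and 694 lower, and 51 of them differed by 2-fold or more (30 higher, 21 lower).

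Other large rises in PGC-1a3 were Pld4 (1.57 ± 0.14), the immune ligand gene Tnfsf9 (1.46 ± 0.20), H2-DMa (1.19 ± 0.12), which encodes an antigen-loading protein, Atp1b4 (1.17 ± 0.21), Gpnmb (1.14 ± 0.10) and Mrgprf (1.13 ± 0.13). Other large falls were the adhesion gene Emb (-1.28 ± 0.21), Atp13a4 (-1.25 ± 0.12), Clic5 (-1.22 ± 0.10), the matrix gene Tnc (-1.17 ± 0.15), the lipoprotein receptor gene Vldlr (-1.14 ± 0.13) and the slow myosin light chain gene Myl2 (-1.12 ± 0.21).

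Among cell cycle genes, 11 of 30 measured genes rose and 0 fell (12 and 0 adjusted over the list alone) in PGC-1a3, including Mcm5 (1.12 ± 0.10) and Mcm4 (1.10 ± 0.11). The cell cycle median was 0.13 log2 (adjusted p = 4.5e-05 by camera, and adjusted p = 0.55 with an estimated correlation). Among splicing factors, 10 of 38 measured genes rose and 1 fell (16 and 2 adjusted over the list alone), with Celf1 at 0.42 ± 0.05, Khdrbs1 at 0.37 ± 0.06 and Rbfox1, a muscle and brain splicing regulator gene, at -0.41 ± 0.08. The splicing factor median was 0.19 log2 (adjusted p = 0.00023 by camera, and adjusted p = 0.55 with an estimated correlation). In branched-chain amino acid catabolism, 0 of 20 measured genes rose and 4 fell (0 and 13 adjusted over the list alone), including Pcca (-0.64 ± 0.12). The branched-chain amino acid median was -0.24 log2 (adjusted p = 0.00023 by camera, and adjusted p = 0.55 with an estimated correlation).

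Among slow-fibre contractile genes, 0 of 10 measured genes rose and 3 fell (0 and 8 adjusted over the list alone) in PGC-1a3, including Pln and Myl2. The slow-fibre median was -0.19 log2 (adjusted p = 0.00023 by camera, and adjusted p = 0.55 with an estimated correlation). Among fast-fibre contractile genes, 0 of 14 measured genes rose and 2 fell (0 and 6 adjusted over the list alone), including Casq1 (-0.93 ± 0.10). The fast-fibre median was -0.14 log2 (adjusted p = 0.0064 by camera, and adjusted p = 0.55 with an estimated correlation), and the adjusted p was 0.07 without GFP replicate 1. In myogenic differentiation, 0 of 15 measured genes rose and 4 fell (0 and 5 adjusted over the list alone), including Myf6 (-0.46 ± 0.08). The myogenic median was -0.09 log2 (adjusted p = 0.013 by camera, and adjusted p = 0.55 with an estimated correlation), and the adjusted p was 0.088 without GFP replicate 1 and 0.079 without PGC-1a3 replicate 3. In the unfolded protein and integrated stress response, 0 of 23 measured genes rose and 3 fell (2 and 8 adjusted over the list alone), including Sel1l (-0.44 ± 0.06). The unfolded protein response median was -0.14 log2 (adjusted p = 0.014 by camera, and adjusted p = 0.6 with an estimated correlation), and the adjusted p was 0.057 with fry in place of camera, and 0.088 without GFP replicate 1 and 0.12 without PGC-1a3 replicate 3.

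In PGC-1a3, 7 of the 28 lists passed, 2 up and 5 down, and this number was 0 with an estimated correlation, 4 without GFP replicate 1, 14 without GFP replicate 2, 13 with quantile normalization, 13 with a filter at the median signal, 15 with the interquartile-range covariate and 11 by fry. With only the 2 groups in the fit, 36 clusters passed, and the adjusted p was 0.058 for Dmd, 0.058 for Pld4, 0.054 for H2-DMa, 0.11 for Atp1b4, 0.1 for Emb, 0.14 for Myl2, 0.1 for Celf1, 0.12 for Khdrbs1, 0.11 for Rbfox1, 0.17 for Pcca, 0.098 for Myf6 and 0.1 for Sel1l. Leaving out GFP replicate 3 gave 1129 clusters, leaving out PGC-1a3 replicate 1 or 2 gave 865 and 928, median centring gave 1127 and array weights gave 3072. The interquartile-range covariate gave 1072 higher and 1181 lower, and the fit of 2 groups gave 14 and 22.

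PGC-1a4 against GFP asks what the isoform studied for muscle growth changed. The genes that fell included Nqo1 of antioxidant defence, Trib3 of the stress response and the helicase gene Mcm6, and those that rose included Cpt1a and Hk1, which act in fuel use. Slc7a11, the cystine transporter gene, changed by -3.71 ± 0.24 log2 (SE, n = 3 per group, adjusted p = 2e-06) and Nqo1 by -3.05 ± 0.20 (adjusted p = 2e-06). Elovl7 rose by 2.34 ± 0.15 (adjusted p = 1.7e-06) and Map2k6, which encodes a kinase that activates p38, by 1.84 ± 0.12 (adjusted p = 2.3e-06). In all, 3331 clusters passed, 1646 higher and 1685 lower, and 182 of them differed by 2-fold or more (76 higher, 106 lower).

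Other large rises in PGC-1a4 were Necab1 (2.21 ± 0.13), Cend1 (2.11 ± 0.16), Pipox (1.94 ± 0.15), Glrx (1.92 ± 0.12), the aspartoacylase gene Aspa (1.86 ± 0.16) and Pdk4 (1.66 ± 0.13). As stated above, Pipox is not shown to be above background in GFP. Other large falls were Atp13a4 (-2.86 ± 0.12), Upk1b (-2.53 ± 0.17), Ptgs2 (-2.51 ± 0.21), Hspa1a (-2.41 ± 0.10), the relaxin receptor gene Rxfp1 (-1.94 ± 0.15) and Tnfsf18 (-1.86 ± 0.20). The myostatin gene Mstn fell by 1.58 log2 (SE 0.14) and the follistatin gene Fst by 1.13 (SE 0.08), while the receptor gene Adgrg1 rose by 1.13 ± 0.08. Their list, muscle growth, did not pass as a group by camera (adjusted p = 0.94). This test asks whether a list moves 1 way, and the list holds both Mstn and the gene of its antagonist, Fst. The result therefore does not show whether growth signalling changed.

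In glycolysis and glucose uptake, 8 of 18 measured genes rose and 1 fell (8 and 1 adjusted over the list alone) in PGC-1a4, including the hexokinase gene Hk1 (0.84 ± 0.07) and Pfkp (0.71 ± 0.07). The glycolysis median was 0.35 log2 (adjusted p = 4.3e-05 by camera, and adjusted p = 0.3 with an estimated correlation). In fatty acid oxidation, 9 of 23 measured genes rose and 2 fell (13 and 3 adjusted over the list alone), including Cpt1a (1.22 ± 0.06) and Slc25a20 (0.86 ± 0.11). The fatty acid oxidation median was 0.31 log2 (adjusted p = 2.2e-05 by camera, and adjusted p = 0.3 with an estimated correlation). In the TCA cycle, 7 of 21 measured genes rose and 0 fell (9 and 0 adjusted over the list alone), including Idh3a (0.99 ± 0.07) and Ogdh (0.59 ± 0.06). The TCA cycle median was 0.18 log2 (adjusted p = 2.9e-05 by camera, and adjusted p = 0.34 with an estimated correlation). In branched-chain amino acid catabolism, 8 of 20 measured genes rose and 0 fell (10 and 0 adjusted over the list alone), including Bckdhb (1.15 ± 0.10). The branched-chain amino acid median was 0.23 log2 (adjusted p = 6.9e-06 by camera, and adjusted p = 0.34 with an estimated correlation). In the malate-aspartate shuttle and kynurenine aminotransferase list, 5 of 8 measured genes rose and 0 fell (6 and 0 adjusted over the list alone), including Slc25a12 (0.63 ± 0.05). That list's median was 0.49 log2 (adjusted p = 2.2e-05 by camera, and adjusted p = 0.3 with an estimated correlation).

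In mitochondrial dynamics, 4 of 13 measured genes rose and 0 fell (5 and 0 adjusted over the list alone) in PGC-1a4, including Mfn1 (0.93 ± 0.09). The mitochondrial dynamics median was 0.16 log2 (adjusted p = 0.011 by camera, and adjusted p = 0.34 with an estimated correlation), and the adjusted p was 0.065 with a filter at the median signal, 0.12 with array weights and 0.051 with the interquartile-range covariate, and 0.12 without GFP replicate 2. In oxidative phosphorylation, 8 of 52 measured genes rose and 0 fell (8 and 0 adjusted over the list alone), including Uqcr10 (0.54 ± 0.10). The oxidative phosphorylation median was 0.07 log2 (adjusted p = 0.025 by camera, and adjusted p = 0.62 with an estimated correlation), and the adjusted p was 0.13 with quantile normalization, 0.13 with a filter at the median signal, 0.15 with array weights and 0.1 with the interquartile-range covariate, and 0.21 without GFP replicate 2 and 0.068 without PGC-1a4 replicate 2. In cholesterol and fatty acid synthesis, 6 of 23 measured genes rose and 1 fell (7 and 1 adjusted over the list alone), including the acetyl-CoA carboxylase gene Acacb (0.96 ± 0.06). The cholesterol and fatty acid synthesis median was 0.04 log2 (adjusted p = 0.019 by camera, and adjusted p = 0.76 with an estimated correlation), and the adjusted p was 0.058 with quantile normalization, 0.1 with a filter at the median signal, 0.29 with array weights and 0.1 with the interquartile-range covariate, and 0.19 without GFP replicate 2, 0.058 without PGC-1a4 replicate 1 and 0.057 without PGC-1a4 replicate 3.

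Among cell cycle genes, 0 of 30 measured genes rose and 12 fell (0 and 18 adjusted over the list alone) in PGC-1a4, including Mcm6 (-1.15 ± 0.12), Mcm3 (-0.92 ± 0.10) and Birc5 (-0.69 ± 0.12). The cell cycle median was -0.39 log2 (adjusted p = 2.7e-06 by camera, and adjusted p = 0.34 with an estimated correlation). In the unfolded protein and integrated stress response, 0 of 23 measured genes rose and 11 fell (1 and 13 adjusted over the list alone), including Trib3 (-1.36 ± 0.15) and the serine synthesis gene Psat1 (-1.03 ± 0.14). The unfolded protein response median was -0.22 log2 (adjusted p = 2.2e-05 by camera, and adjusted p = 0.34 with an estimated correlation). Among p53 targets, 0 of 19 measured genes rose and 8 fell (1 and 9 adjusted over the list alone), including Plk2 (-1.45 ± 0.09) and Plk3 (-1.18 ± 0.09). The p53 target median was -0.19 log2 (adjusted p = 0.00032 by camera, and adjusted p = 0.3 with an estimated correlation). In antioxidant defence, 3 of 18 measured genes rose and 7 fell (3 and 7 adjusted over the list alone), with Hmox1, the haem oxygenase gene, at -1.68 ± 0.11 and Gclc at -0.82 ± 0.08. The antioxidant median was -0.16 log2 (adjusted p = 0.062 by camera, and adjusted p = 0.34 with an estimated correlation), so the list did not pass.

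In PGC-1a4, 11 of the 28 lists passed, 8 up and 3 down, and 0 with an estimated correlation. With only the 2 groups in the fit, 1014 clusters passed. Median centring gave 1504 higher and 975 lower, against 1466 and 1223 without GFP replicate 1, 1356 and 1175 without GFP replicate 3, 1314 and 1289 without PGC-1a4 replicate 2 and 1392 and 1957 without GFP replicate 2.

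**Figure D2:**
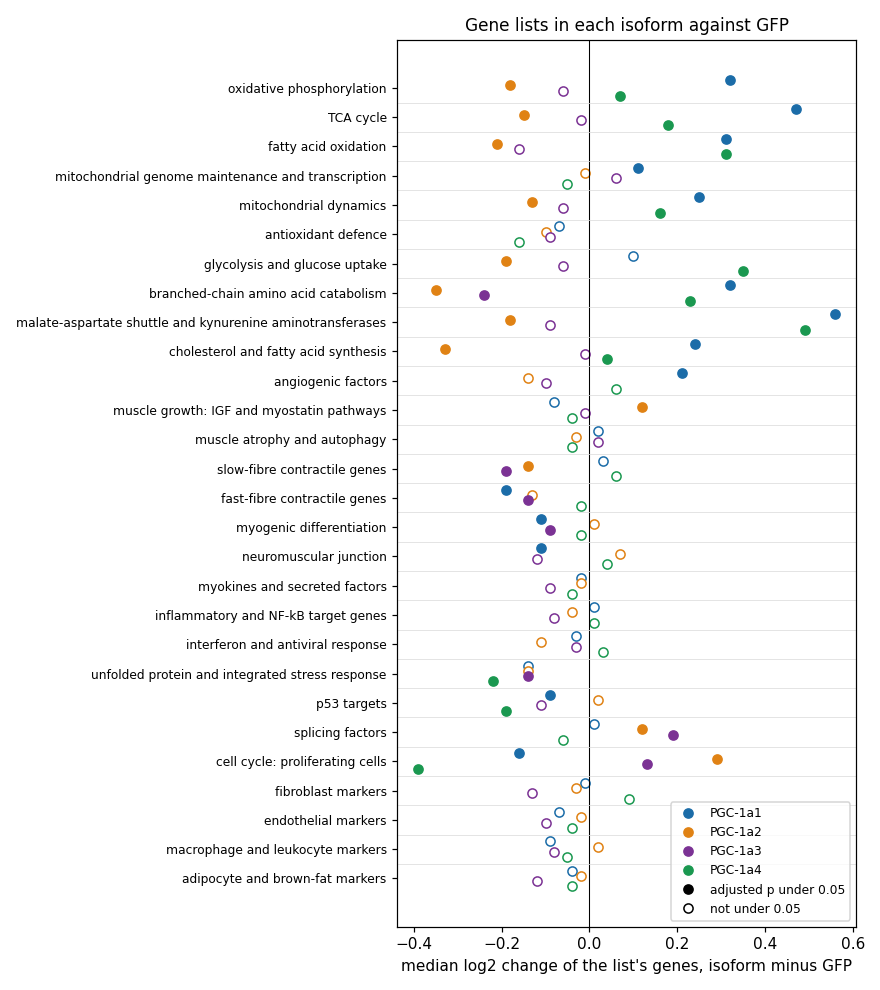
Median log2 change of each of the 28 gene lists (rows) in each isoform against GFP (n = 3 arrays per group), with filled points where the camera adjusted p was under 0.05 with the preset correlation. The TCA cycle median was 0.47 in PGC-1a1 and -0.15 in PGC-1a2, and the cell cycle median was 0.29 in PGC-1a2 and -0.39 in PGC-1a4.

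Across the isoforms, 44 list results passed against GFP, 3 of them also with an estimated correlation, and 9 of the 28 lists passed in none of the 4. Antioxidant defence had adjusted p between 0.062 and 0.89, muscle atrophy and autophagy between 0.89 and 0.97, myokines and secreted factors between 0.24 and 1, and inflammatory and NF-kB targets between 0.74 and 0.94. Interferon and antiviral genes, a possible mark of the vector, had adjusted p between 0.42 and 0.93. The marker lists of other cell types had adjusted p from 0.08 to 0.56 for fibroblasts, 0.44 to 0.97 for endothelium, 0.23 to 0.95 for macrophages and leukocytes, and 0.17 to 0.88 for adipocytes. In 17 of the 112 list results the median, the mean and the test differed in sign, and 0 of the 17 passed. Among them, the PGC-1a1 antioxidant list had a median of -0.07 and a mean of 0.004, and the PGC-1a2 angiogenic list had a median of -0.14 and a mean of 0.018.

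The isoforms were then compared directly, since a call in 1 isoform and not in another does not show a difference. PGC-1a1 against PGC-1a2 gave 4488 clusters, 2388 higher in PGC-1a1 and 2100 lower. Elovl7 (3.69 ± 0.15 log2, SE, n = 3 per group), Nudt19 (2.32 ± 0.13), Hpdl (2.21 ± 0.26) and Cend1 (2.21 ± 0.16) were higher in PGC-1a1. Pla2g7 (-2.68 ± 0.10), Selp (-2.55 ± 0.10), Ptgs2 (-2.49 ± 0.21) and Palmd (-2.16 ± 0.21) were lower. In oxidative phosphorylation, 38 of 52 measured genes were higher and 0 were lower (42 and 0 adjusted over the list alone). The oxidative phosphorylation median was 0.51 log2 (adjusted p = 2.3e-19 by camera, and adjusted p = 0.047 with an estimated correlation). In the TCA cycle, 20 of 21 measured genes were higher and 0 were lower (20 and 1 adjusted over the list alone). The TCA cycle median was 0.68 log2 (adjusted p = 1.6e-15 by camera, and adjusted p = 0.088 with an estimated correlation). In the cell cycle list, 3 of 30 measured genes were higher and 18 were lower (3 and 21 adjusted over the list alone). The cell cycle median was -0.46 log2 (adjusted p = 6.4e-08 by camera, and adjusted p = 0.25 with an estimated correlation). In all 16 lists passed, 11 up and 5 down, and 15 of them had adjusted p between 0.088 and 0.61 with an estimated correlation. Median centring gave 2375 higher and 1306 lower clusters, and without PGC-1a1 replicate 1 there were 1815 and 1829.

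PGC-1a1 against PGC-1a3 gave 3277 clusters, 1513 higher in PGC-1a1 and 1764 lower. Elovl7 (3.21 ± 0.15), Hpdl (2.26 ± 0.26), Cend1 (2.21 ± 0.16) and Pln (2.16 ± 0.19) were higher in PGC-1a1, and Tnfsf9 (-2.09 ± 0.20), Mcm3 (-2.06 ± 0.10), Mcm6 (-1.77 ± 0.12) and Upk1b (-1.75 ± 0.17) were lower. In oxidative phosphorylation, 35 of 52 measured genes were higher and 0 were lower (42 and 0 adjusted over the list alone). The oxidative phosphorylation median was 0.36 log2 (adjusted p = 2.7e-20 by camera, and adjusted p = 0.04 with an estimated correlation). Among slow-fibre contractile genes, 6 of 10 measured genes were higher and 0 were lower (6 and 0 adjusted over the list alone). The slow-fibre median was 0.25 log2 (adjusted p = 0.00094 by camera, and adjusted p = 0.2 with an estimated correlation). In all 12 lists passed, 10 up and 2 down, and 11 of them had adjusted p between 0.053 and 0.5 with an estimated correlation. Fitted on the 2 groups, 2097 clusters passed, and array weights gave 5346. Without PGC-1a1 replicate 2 or 3 or PGC-1a3 replicate 1 the numbers were 2151 (1108 higher, 1043 lower), 2123 (1109 and 1014) and 2181 (1157 and 1024), without PGC-1a3 replicate 2 there were 1168 higher and 1128 lower, and median centring gave 1389 higher and 833 lower.

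PGC-1a1 against PGC-1a4 gave 2119 clusters, 1235 higher in PGC-1a1 and 884 lower. Slc7a11 (2.39 ± 0.24), Hpdl (2.13 ± 0.26), Atp13a4 (2.00 ± 0.12) and Tnfsf18 (1.86 ± 0.20) were higher in PGC-1a1, and Necab1 (-1.74 ± 0.13), H2ac6 (-1.27 ± 0.24), Pdk4 (-1.15 ± 0.13) and Tspan1 (-1.15 ± 0.21) were lower. In oxidative phosphorylation, 19 of 52 measured genes were higher and 0 were lower (30 and 0 adjusted over the list alone). The oxidative phosphorylation median was 0.24 log2 (adjusted p = 5.2e-12 by camera, and adjusted p = 0.15 with an estimated correlation). In antioxidant defence, 7 of 18 measured genes were higher and 1 were lower (10 and 1 adjusted over the list alone). The antioxidant median was 0.26 log2 (adjusted p = 0.00013 by camera, and adjusted p = 0.15 with an estimated correlation). In glycolysis and glucose uptake, 0 of 18 measured genes were higher and 5 were lower (0 and 8 adjusted over the list alone). The glycolysis median was -0.15 log2 (adjusted p = 0.00035 by camera, and adjusted p = 0.38 with an estimated correlation). In all 8 lists passed, 6 up and 2 down, and the 8 had adjusted p between 0.15 and 0.55 with an estimated correlation. Fitted on the 2 groups, 910 clusters passed, median centring gave 1364, array weights 3358 and the interquartile-range covariate 1521 higher and 1604 lower. Without PGC-1a1 replicate 1, 2 or 3 the numbers were 1355, 1264 and 1412, and without PGC-1a4 replicate 3 the number was 1217.

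PGC-1a2 against PGC-1a3 gave 2164 clusters, 877 higher in PGC-1a2 and 1287 lower. Selp (2.24 ± 0.10), Tnfrsf12a (1.91 ± 0.12), Pla2g7 (1.89 ± 0.10) and Prr9 (1.78 ± 0.17) were higher in PGC-1a2, and Ak4 (-1.60 ± 0.17) and Postn (-1.19 ± 0.12) were lower. Prr9 averaged 3.65 log2 in PGC-1a3, below the lower quartile of each array (3.857 to 4.047), so it is not shown to be above background there. Ifit1, an interferon-induced gene, averaged 2.66 ± 0.44 log2 (SD) in PGC-1a2 and 4.17 ± 0.52 in PGC-1a3 (adjusted p = 0.026), with adjusted p of 0.075 without PGC-1a2 replicate 2, 0.098 without PGC-1a2 replicate 3, 0.1 without PGC-1a3 replicate 1, 0.073 without PGC-1a3 replicate 3 and 0.068 with only the 2 groups. The lower level lay below the lower quartile of each array (3.857 to 4.047), so it is not shown to be above background. Nubpl differed by -1.46 ± 0.35 (adjusted p = 0.024), with 0.052, 0.052 and 0.09 without PGC-1a2 replicate 1, 2 or 3, 0.096 and 0.099 without PGC-1a3 replicate 1 or 2, and 0.059 with only the 2 groups. In the muscle growth list, 7 of 24 measured genes were higher and 1 were lower (11 and 2 adjusted over the list alone). The muscle growth median was 0.17 log2 (adjusted p = 3e-04 by camera, and adjusted p = 0.38 with an estimated correlation). At the neuromuscular junction, 9 of 20 measured genes were higher and 0 were lower (9 and 2 adjusted over the list alone). The neuromuscular junction median was 0.21 log2 (adjusted p = 0.00024 by camera, and adjusted p = 0.45 with an estimated correlation). In all 7 lists passed, 4 up and 3 down, and the 7 had adjusted p between 0.38 and 0.87 with an estimated correlation. Fitted on the 2 groups, 693 clusters passed, median centring gave 1215 and array weights 4009. Without PGC-1a2 replicate 1, 2 or 3 the numbers were 1405, 1219 and 1386, and without PGC-1a3 replicate 1 or 2 they were 1133 and 1105.

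PGC-1a2 against PGC-1a4 gave the largest number among the 10 contrasts, 5878 clusters, 2937 higher in PGC-1a2 and 2941 lower. Slc7a11 (4.13 ± 0.24), Ptgs2 (3.35 ± 0.21), Pla2g7 (2.97 ± 0.10) and Nqo1 (2.89 ± 0.20) were higher in PGC-1a2. Necab1 (-2.65 ± 0.13), Map2k6 (-2.48 ± 0.12), Ak4 (-2.38 ± 0.17) and the synaptic vesicle gene Rab3a (-2.32 ± 0.09) were lower. Pla2g7 averaged 3.85 log2 in PGC-1a4, below the lower quartile of each array. In the cell cycle list, 22 of 30 measured genes were higher and 0 were lower (24 and 0 adjusted over the list alone). The cell cycle median was 0.77 log2 (adjusted p = 2.4e-10 by camera, and adjusted p = 0.25 with an estimated correlation). In branched-chain amino acid catabolism, 0 of 20 measured genes were higher and 18 were lower (0 and 19 adjusted over the list alone). The branched-chain amino acid median was -0.50 log2 (adjusted p = 9.4e-10 by camera, and adjusted p = 0.25 with an estimated correlation). In all 12 lists passed, 3 up and 9 down, and the 12 had adjusted p between 0.25 and 0.41 with an estimated correlation.

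PGC-1a3 against PGC-1a4 gave 5365 clusters, 3080 higher in PGC-1a3 and 2285 lower. Nqo1 (2.93 ± 0.20), Slc7a11 (2.88 ± 0.24), Pld4 (2.52 ± 0.14) and the protease inhibitor gene Serpinb9b (2.48 ± 0.17) were higher in PGC-1a3. Myl2 (-2.42 ± 0.21), Necab1 (-2.26 ± 0.13), Pdk4 (-2.24 ± 0.13) and Map2k6 (-2.23 ± 0.12) were lower. In fatty acid oxidation, 1 of 23 measured genes were higher and 14 were lower (2 and 17 adjusted over the list alone). The fatty acid oxidation median was -0.41 log2 (adjusted p = 1.8e-05 by camera, and adjusted p = 0.33 with an estimated correlation). Among slow-fibre contractile genes, 0 of 10 measured genes were higher and 6 were lower (1 and 6 adjusted over the list alone). The slow-fibre median was -0.28 log2 (adjusted p = 0.0031 by camera, and adjusted p = 0.33 with an estimated correlation). In all 10 lists passed, 2 up and 8 down, and the 10 had adjusted p between 0.33 and 0.53 with an estimated correlation.

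The calls against GFP were also compared between isoforms. PGC-1a1 and PGC-1a4 shared 599 higher and 347 lower clusters, where independent calls would share 73.1 and 40.4. In this pair 21 moved in opposite directions (114 if independent). For PGC-1a4 the source name says isoform 1, in conflict with the titles that were followed. PGC-1a2 and PGC-1a3 shared 350 higher and 285 lower clusters (53.4 and 33.1 if independent), with 29 opposite (87.5 if independent). PGC-1a2 and PGC-1a4 shared 109 higher and 103 lower clusters (75.1 and 80.4 if independent), and 702 moved in opposite directions (155 if independent). PGC-1a1 and PGC-1a3 shared 148 higher and 141 lower clusters (52 and 16.7 if independent), with 93 opposite (58.9 if independent). PGC-1a1 and PGC-1a2 shared 84 and 72 (47.2 and 26.7 if independent), with 275 opposite (75 if independent), and PGC-1a3 and PGC-1a4 shared 143 and 131 (82.6 and 50.1 if independent), with 436 opposite (134 if independent). The 4 comparisons share the GFP arrays, and 20 simulated data sets with unchanged groups shared at most 2.3 higher and 2.8 lower clusters on average for a pair. As no group changed in these sets, they cannot show how many shared calls the common GFP arrays give when groups do change. The covariance of the log2 changes was 0.0453 for PGC-1a1 with PGC-1a4 and 0.0359 for PGC-1a2 with PGC-1a3, against 0.0287 in the simulated sets. It was below the simulated value in the other 4 pairs: 0.0233 for PGC-1a1 with PGC-1a3, where the shared clusters exceeded independence all the same, 0.014 for PGC-1a1 with PGC-1a2 (0.0288 simulated), 0.0127 for PGC-1a3 with PGC-1a4 and 0.00356 for PGC-1a2 with PGC-1a4. The correlation across clusters, which are not independent replicates, was below its simulated value in all 6 pairs, among them 0.57 against 0.605 for PGC-1a1 with PGC-1a4, 0.509 against 0.608 for PGC-1a2 with PGC-1a3 and 0.34 against 0.593 for PGC-1a1 with PGC-1a3. As the simulated sets hold no true change, a change in 1 isoform alone also lowers this correlation. A value below the simulated one therefore does not show that isoforms are less alike. As 3 controls cannot be split into independent sets of 2 or more, part of the excess in shared clusters and covariance may come from the shared controls. Arrays of the 2 groups did not overlap for 22.3% to 26.2% of clusters in the comparisons with GFP, against 10% by chance.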

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

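The test of array signal spread, the tests of fibroblast markers and the tests of GFP replicate 2 as the whole cause were chosen after the result was seen, the rules for reading the fibroblast markers and the cell cycle list without GFP replicate 2 were tightened after their first values were seen, and the replication and mitosis lists were written after the cell cycle result was seen.

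A list is given here because it passed against GFP in both isoforms of a pair, with means of opposite sign. The direct contrast also passed the threshold by camera at the preset correlation. The widest such pair is given for each. Other lists differed in sign with the direct contrast past the threshold, but did not pass against GFP in both isoforms. Among them, muscle growth had means of -0.091 in PGC-1a1 and 0.162 in PGC-1a2 (direct adjusted p = 0.00024, and 0.1 with an estimated correlation). Slow-fibre genes had means of 0.147 in PGC-1a1 and -0.383 in PGC-1a3 (direct adjusted p = 0.00094, and 0.2 with an estimated correlation). The mean change of oxidative phosphorylation genes was 0.325 log2 in PGC-1a1 and -0.166 in PGC-1a2, a difference of 0.491 (adjusted p = 2.3e-19, and adjusted p = 0.047 with an estimated correlation). For the TCA cycle the same difference was 0.652 (adjusted p = 1.6e-15, and 0.088 with an estimated correlation). Fatty acid oxidation differed by 0.453 (adjusted p = 5.5e-08, and 0.088 with an estimated correlation) and mitochondrial dynamics by 0.386 (adjusted p = 0.00011, and 0.14 with an estimated correlation). The malate-aspartate shuttle and kynurenine aminotransferase list differed by 0.724 (adjusted p = 4.9e-07, and 0.088 with an estimated correlation), and cholesterol and fatty acid synthesis by 0.435 (adjusted p = 7.4e-06, and 0.25 with an estimated correlation). Between PGC-1a2 and PGC-1a4, branched-chain amino acid catabolism differed by -0.73 (adjusted p = 9.4e-10, and 0.25 with an estimated correlation). In the same contrast the cell cycle list differed by 0.744 (adjusted p = 2.4e-10, and 0.25 with an estimated correlation) and glycolysis by -0.509 (adjusted p = 3.8e-05, and 0.25 with an estimated correlation).

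DNA replication genes were higher in PGC-1a2 and PGC-1a3: among the 25 members neither on a fixed list nor seen before, 11 rose and 0 fell in PGC-1a3 (13 and 0 adjusted over the list alone), with a median of 0.35 log2 and a camera p of 1.2e-08 (0.063 with an estimated correlation), and 3 rose and 1 fell in PGC-1a2 (5 and 1 adjusted over the list alone), with a median of 0.21 and a camera p of 7.7e-05 (0.18 with an estimated correlation). More cells passing through mitosis would move both groups of genes, so the mitosis median of -0.08 in PGC-1a3 beside a replication median of 0.44 over all 39 members argues against it there. In PGC-1a2 the medians were 0.18 and 0.26, which goes with it. Of 37 mitosis genes, however, 2 rose and 0 fell in PGC-1a2 (camera p = 3e-05, and 0.22 with an estimated correlation). Set directly against PGC-1a3, 10 mitosis genes were higher in PGC-1a2 and 0 were lower (camera p = 8.2e-09, and 0.1 with an estimated correlation). Without GFP replicate 2 the mean of the replication list was 0.246 of 0.302 in PGC-1a2 and 0.404 of 0.459 in PGC-1a3, which argues against that array as the whole cause. Of the 39 members, 34 and 38 stayed above 0. The means with 1 array left out had an SD of 0.048 and 0.057, but they share most arrays, so this understates the sampling error. The list also includes genes seen before. A part of the size stays open, as 0.246 and 0.404 were the lowest of those means. Without that array the cell cycle list mean was 0.285 of 0.359 in PGC-1a2 and 0.247 of 0.32 in PGC-1a3. Fibroblasts in place of myotubes stay open: their markers had medians of -0.03 in PGC-1a2 (quartiles -0.16 and 0.07) and -0.13 in PGC-1a3 (quartiles -0.25 and 0). But 12 of the 18 already lay above the median of all values in GFP (Fn1 at 10.22 and Postn at 8.52), which would hide a small share, and 1 is on another list. Postn itself changed by -1.72 log2 in PGC-1a2. A larger share of undifferentiated myoblasts and an effect of the isoforms on these genes stay open and were not tested. In PGC-1a3 the myogenic, slow-fibre and fast-fibre lists passed by camera as lower, with means of -0.176, -0.383 and -0.147 (adjusted p = 0.55 for each with an estimated correlation). In PGC-1a2 the slow-fibre list did, with a mean of -0.283 (adjusted p = 0.43 with an estimated correlation). The myogenic list there, with a median of 0.01 and a mean of -0.048 (adjusted p = 0.88 by camera), and the fast-fibre list, with a mean of -0.069 (adjusted p = 0.14 by camera), did not. In these lists the myosin heavy chain genes Myh1, Myh2, Myh3, Myh4, Myh7 and Myh8 were not measured.

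GFP replicate 2 stood apart from GFP replicates 1 and 3, and an unlike spread of signal is a candidate explanation. Over the 15 arrays the main axis of within-group deviation, with 29.6% of the within-group sum of squares, followed the deviation in interquartile range (r = -0.942, permutation p = 0.0023, rho = -0.918, permutation p = 0.0035, 7776 within-group permutations, r = -0.892 without the 2 farthest arrays), and the range was 3.69 log2 in this array against 3.82 to 4.03 in the others. The axis and the range are computed from the same array values, so this association does not tell what caused the deviation. GFP replicate 2 scored 0.588 on the axis. Among the arrays on its other side were the replicate 1 arrays of GFP (-0.349), PGC-1a1 (-0.31), PGC-1a3 (-0.286) and PGC-1a4 (-0.219). A mislabelled isoform culture would carry most of an isoform's change, and the highest share was 0.23, which argues against it. RNA of other cell types stays open: the highest median difference was 0.37, for endothelial markers, of which 2 of 14 lay above the median of all values in GFP (the most abundant being Eng at 6.43 and Egfl7 at 5.71) and 0 were on another list. The other marker lists differed by 0.24 for fibroblasts, 0.24 for adipocytes and 0.13 for leukocytes.

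Ppargc1a was little changed in PGC-1a2 and PGC-1a3, by 0.35 and 0.42 log2. Cultures no different from GFP would call as many clusters under other groupings of the 9 arrays. Only 1 of 100 splits, the labelled one, reached its 1740 clusters by the F-test, against 35 in the highest other split. A chance division of these arrays can be excluded for the 3 groups together. Chance differences between cultures cannot, as the labels do not say whether replicates are separate cultures. The F-test also does not show that each isoform differed from GFP. With only the 2 groups fitted, 173 clusters were called in PGC-1a2 and 36 in PGC-1a3. Probes outside the parts that these isoforms share, a lower dose of virus and a lower yield of transcript stay open and were not tested.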

How the results depend on the processing

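All alternatives were chosen before the data were examined except the interquartile-range covariate, which was added after GFP replicate 2 was seen to stand apart. Of 444 called results for named genes, 217 kept their call under every setting, and of 44 list results past the threshold 3 did, with 0 lists reversed. The cause of the changes below was not tested. Fewer arrays leave fewer residual degrees of freedom, but the fits of 2 groups, which all leave equally few, fell by unlike amounts.

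With only the 2 groups of a contrast fitted, 393 clusters were called in PGC-1a1, 173 in PGC-1a2, 36 in PGC-1a3 and 1014 in PGC-1a4 against GFP, and 2097 in PGC-1a1 against PGC-1a3, 910 in PGC-1a1 against PGC-1a4 and 693 in PGC-1a2 against PGC-1a3. The other isoform pairs kept 3869 of 4488 (PGC-1a1 and PGC-1a2), 5204 of 5878 (PGC-1a2 and PGC-1a4) and 4133 of 5365 (PGC-1a3 and PGC-1a4). Median within-group SD was 0.176 log2 in GFP and 0.113 to 0.137 in the isoform groups. Whether this explains the larger drops against GFP was not tested. Array weights gave 2994, 3492 and 3072 in PGC-1a1, PGC-1a2 and PGC-1a3 against GFP, and 5346, 3358 and 4009 in the same 3 isoform pairs. Median centring gave 1354 in PGC-1a2, 1127 in PGC-1a3, 1364 in PGC-1a1 against PGC-1a4 and 1215 in PGC-1a2 against PGC-1a3. The interquartile-range covariate gave 2430 in PGC-1a1 and 3350 in PGC-1a2. The replicate block gave 1598, 2160, 1828 and 3354 clusters in the 4 isoforms against GFP.

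With an estimated correlation 3 lists passed in PGC-1a1, 0 in PGC-1a2, 0 in PGC-1a3 and 0 in PGC-1a4. In PGC-1a3 the lists past the threshold were 13 with quantile normalization, 13 with the filter at the median, 15 with the interquartile-range covariate and 11 by fry. With 1 array left out, list numbers ran from 11 to 15 in PGC-1a1, 10 to 14 in PGC-1a2, 4 to 14 in PGC-1a3 and 8 to 11 in PGC-1a4.

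The direction split moved too. In PGC-1a1, 64.9% of called clusters were higher, against 83.8% with median centring, 47.4% with array weights, 50% with the covariate and 54.5% without GFP replicate 2. In PGC-1a2 it was 48.9%, against 58.3% with median centring, 59.5% with the 2 groups alone, 52% with quantile normalization, 42.3% with array weights and 38.6% without GFP replicate 2, and in PGC-1a4 49.4%, against 60.7% with median centring and 41.6% without GFP replicate 2. In PGC-1a3 it was 62.8%, against 38.9% with the 2 groups alone, 47.6% with the covariate and 50.5% without GFP replicate 2. Quantile normalization turned the larger direction in PGC-1a1 against PGC-1a2 (2437 higher, 2519 lower), PGC-1a2 against PGC-1a3 (1237 and 1229) and PGC-1a2 against PGC-1a4 (3240 and 3054).

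Leaving out 1 array gave from 951 to 1490 clusters in PGC-1a1, 1231 to 2122 in PGC-1a2, 865 to 1620 in PGC-1a3 and 2474 to 3349 in PGC-1a4. Between isoforms it gave 3393 to 3801 (PGC-1a1 and PGC-1a2), 2123 to 2707 (PGC-1a1 and PGC-1a3), 1217 to 1669 (PGC-1a1 and PGC-1a4), 1105 to 1902 (PGC-1a2 and PGC-1a3), 4891 to 5242 (PGC-1a2 and PGC-1a4) and 4350 to 5107 (PGC-1a3 and PGC-1a4). For the F-test it was 6365 to 7885.

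The Ppargc1a change ran from 3.88 to 4.26 in PGC-1a1, 0.14 to 0.53 in PGC-1a2, 0.21 to 0.59 in PGC-1a3 and 1.73 to 2.11 in PGC-1a4 with 1 array left out. Its difference of -0.07 between PGC-1a2 and PGC-1a3, which did not pass, became 0.05 with the interquartile-range covariate, and ran from -0.14 to 0.03 with 1 array left out. Clusters near the background cannot be told from absent ones, as the background level is not given in the sources used here.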

Other observations

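The tests of NRF2 targets and heat shock genes were chosen after the result was seen, and 4 genes seen before the lists were written were left out of them after their first values were known.

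Nqo1 and Slc7a11, targets of the antioxidant regulator NRF2, and the heat shock gene Hspa1a fell in PGC-1a1 and PGC-1a4, so both gene groups may be lower there. Among heat shock genes on no fixed list, not named and not seen before (18 measured), the mean change was -0.203 log2 in PGC-1a1, where 5 fell and 0 rose (8 and 0 adjusted over the list alone), with a camera p of 5.6e-06 (0.0047 with an estimated correlation). In PGC-1a4 it was -0.245, where 10 fell and 0 rose (12 and 0 adjusted over the list alone), with a camera p of 1.2e-05 (0.0058 with an estimated correlation). Among NRF2 targets chosen the same way (24 measured), the mean was -0.214 in PGC-1a4, where 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a camera p of 0.0018 (0.049 with an estimated correlation). In PGC-1a1 it was -0.087, where 0 fell and 1 rose (3 and 1 adjusted over the list alone), with a camera p of 0.041 (0.17 with an estimated correlation), a weaker result. Over the whole lists, the heat shock median was 0.01 in PGC-1a2 (with a camera p of 0.67) and -0.03 in PGC-1a3 (with a camera p of 0.31), and the NRF2 median 0.04 (with a camera p of 0.073) and -0.04 (with a camera p of 0.54). Whether these genes fell through less stress, through the coactivator or through the vectors was not tested.

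PGC-1a4 moved many clusters in the direction of PGC-1a1, and it might act as a weaker form. Of the 3331 clusters called in PGC-1a4, 1280 (38.4%) moved farther from GFP than in PGC-1a1 with the direct contrast past the threshold, 574 higher and 706 lower. An action of the same kind that is smaller on each cluster forbids this for so many clusters, so the values argue against that. The clusters were chosen by their call in PGC-1a4 and the doses are not known, so activity at an equal dose was not tested.

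Splits of 3 arrays against 3 number 10, too few for a share under 0.05. The labelled split and the highest other split called 1596 and 5 clusters in PGC-1a1 against GFP, 2177 and 0 in PGC-1a2, 1865 and 0 in PGC-1a3, and 3331 and 2 in PGC-1a4. For the pairs they called 4488 and 0 (PGC-1a1 and PGC-1a2), 3277 and 1 (PGC-1a1 and PGC-1a3), 2119 and 0 (PGC-1a1 and PGC-1a4), 2164 and 0 (PGC-1a2 and PGC-1a3), 5878 and 0 (PGC-1a2 and PGC-1a4) and 5365 and 0 (PGC-1a3 and PGC-1a4). In each of these 1 of the 10 splits, the labelled one, reached its own number. Over the 5 groups, 1 of 100 splits reached 7295 clusters by the F-test, the highest other being 766. A chance division of these arrays can thus be excluded. Chance differences between cultures cannot, as the labels do not say whether replicates are separate cultures.

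For lists past the threshold, splits as large numbered 1 of 10 in PGC-1a1 (14 lists, highest other 12), 2 in PGC-1a2 (12, highest other 14), 3 in PGC-1a3 (7, highest other 16) and 2 in PGC-1a4 (11, highest other 11). The 10 splits are too few for a share under 0.05 here as well. In PGC-1a2, PGC-1a3 and PGC-1a4 another grouping of the arrays passed as many lists as the labels or more. The number of lists past camera at the preset correlation therefore does not set the labels apart from other groupings there.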
